A study of Labroides dimidiatus with 23 samples.

How the data were processed

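H3K27ac CUT&RUN was done on forebrain of adult cleaner wrasse with a commercial kit, and input DNA was prepared by nuclease digestion, per the labels' protocols. Libraries carried adapters with molecular identifiers and were sequenced as read pairs. The submitters' processing notes name Trimmomatic 0.39, FastQC, Bowtie2, SAMtools, Picard and MACS2. The genome build, the MACS2 settings and whether input served as control are not given in the sources used here. Peaks were called by the authors for each library separately, so that fish remain separate replicates. The number that opens each title was taken as a fish number. Nothing else states that libraries come from different fish, so p-values measure the spread between libraries, which may in part be technical.

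Each deposited list gives the start and end of every peak. The score the authors deposited for each peak is, in nearly all rows, 10 times the deposited -log10 q value without decimals. The fold enrichment deposited by the authors is a ratio of signal over background for the peak. The deposited -log10 p and -log10 q values are the peak caller's, and no listed -log10 q was below 1, so the lists end at q = 0.1. Fold and q values are the authors' own and were used only to rank or filter peaks within a list. A library with fewer reads gives fewer and narrower peaks, and read depth is unknown here, so no interval for counting error is given.

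Groups and fish numbers were taken from titles. The tests and the rule for named regions were chosen at the same time as the alternatives given at the end. Libraries with under 0.5 times the median number of peaks (45859) were left out of the tests of regions and of the Jaccard index, which removed familiar 30 replicate 2. Bases covered in at least 3 kept libraries were joined over gaps of up to 200 bp, and pieces of at least 200 bp formed the regions. The mitochondrial genome was left out of regions and covered length. The percent of each region covered by a library's peaks was tested with limma 3.58.1 in R 4.3.3, with the 4 groups in a single model, on 52924 regions with a mean cover of 5 to 95%. This left out 55 regions above 95% and 0 below 5%. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Named regions are the 5 with the smallest p in each of 4 comparisons. Percent cover is bounded and often at 0 or 100, which limma's model does not describe, and Fisher's exact test of presence served as an alternative. Its smallest possible p was 0.00794 at 30 and 0.00217 in the other comparisons, so that at least 8401 regions at 30 and 2292 in the other comparisons would have to reach it to pass adjustment, while 13, 4, 14 and 6 regions did. Peak numbers and covered length were compared over all 23 libraries with two-sided exact permutation tests, and Jaccard indices with a one-sided exact permutation test of within minus between groups. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

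The limma fit was tested on simulated data, in which the real values of 52924 regions were shuffled over libraries region by region and 200 regions were changed. In these, values of 1 group were moved up to at most 100 and those of the other down to at least 0. This narrows the spread within groups. For a median made difference of 69.7 points in the familiar comparison at 30, 49.5% of the changed regions were recovered, and for 36.9 points 0.5%. At 120, 66% were recovered for 70.9 points and 8.5% for 38 points. For 120 against 30, 59.5% were recovered in controls for 69.5 points and 59% in familiar fish for 68.8 points. For 88.9 to 89.4 points 83.5 to 97% were recovered, and for 100 points 100% in each comparison. At 100 points neither group had any spread left, so that result was fixed in advance. Calls outside the changed regions exceeded the nominal share: at 30, 16 stood beside the 99 recovered at 69.7 points. The first form of this test moved whole libraries between groups and called up to 88 regions outside 200 changed ones, in the familiar comparison at 120. The form by region was added after those calls had been seen. A repeat of the first form with other random draws called up to 56, in the same comparison. All 3 runs are kept. With these group sizes and 200 regions changed at once, 49.5 to 66% of made differences of 68.8 to 70.9 points were thus recovered. Most of those of 36.9 to 39.9 points were missed. Fewer changed regions would face a stricter adjustment, so the share recovered among them may be lower, which was not simulated. Real differences can have a wider spread, such as 74.4% ± 43.3 against 0% ± 0 in the region with the smallest p at 30. For these the recovered shares may be too high. Single calls near the threshold carry more error than their adjusted p states.

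The alternatives chosen before the data were examined were all 23 libraries, only peaks with a -log10 q of at least 5, covered length as a covariate, the range of fish numbers (17 to 29, 43 to 59 and 69 to 80) as a block, both together, array weights, no filter on mean cover, Fisher's exact test at 50% or 1 bp, only the 2 groups compared, regions covered in at least 11 libraries, consensus regions in place of bases for the Jaccard index, and each replicate left out in turn. The ranges of fish numbers are not described as batches in the labels. Leaving out 3 libraries that share regions was added after the data were seen, as were the tests of length classes and chromosome shares and the definition of regions shared by those libraries, for which a stricter form was looked at first. Promoters, genes and gene lists had been planned but were not analysed here, because no gene annotation was used here.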

Results

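Histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by CUT&RUN in the forebrain of adult cleaner wrasse, a reef fish that feeds on parasites of client fish. CUT&RUN cuts out antibody-bound chromatin with a tethered nuclease and sequences the released fragments. The fish had either been familiarised with a client before a social preference test (familiar) or had met neither client before (control). Each library carried the number 30 or 120 in its label, for which no unit is given. That number was read as a time, which is an assumption, and is called the time label below. The 23 libraries comprised 6 familiar and 5 control libraries labelled 30, and 6 familiar and 6 control libraries labelled 120. Each library came with its own list of broad peaks. Read depth is unknown, because the lists hold no read counts, so the number and length of peaks describe the lists and not the amount of acetylation. The lists of 22 libraries held between 34714 and 48264 peaks, covering 67.3 to 95.2 Mb. Familiar 30 replicate 2 held 7077 peaks covering 4.70 Mb. It was left out of the comparisons of regions by a rule set on the number of peaks, and the other 22 libraries are called kept libraries.

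The called peaks formed many short regions, few of which were present in all libraries, and fewer long ones, of which a larger share was. Bases covered in at least 3 kept libraries formed 52979 regions with a total length of 133.6 Mb and a median length of 1282 bp. In every kept library, 4817 regions (9.09%, 33.4 Mb) were present, meaning that peaks covered at least 50% of the region. Among the 2144 regions of 10 kb or longer, 975 (45.5%) were present in every kept library, against 300 of 20661 (1.45%) among those under 1 kb. The longest region present in all was 115.8 kb long, on chromosome 1 from 13022127 to 13137891, and was covered by 88.5% ± 4.39 (SD, n = 22). It was followed by 113.9 kb on chromosome 11 from 21638203 to 21752120 (89.6% ± 6.84), 99.9 kb on chromosome 24 from 3192287 to 3292157 (92.3% ± 4.13) and 99.5 kb on chromosome 22 from 12171254 to 12270782 (86.7% ± 4.43). Coordinates are those of the deposited peak lists, whose genome build is not given in the sources used here, and the genes at these places were not analysed here.

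The share of a chromosome's length covered by called peaks was highest on chromosomes 21 and 24, and no test of chromosomes against each other was made. Peaks covered 19.1% ± 1.70 (SD, n = 22) of chromosome 21 and 18.96% ± 1.71 of chromosome 24, measured up to the last peak. The lowest values were 9.13% ± 0.809 on chromosome 19 and 9.80% ± 0.971 on chromosome 23. Chromosome 21 was covered by at least 13.9% in each kept library and chromosome 19 by at most 10.04%.

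The comparison of familiar with control fish at 30 addresses whether prior contact with a client leaves a difference in called forebrain H3K27ac peaks. Here and in the comparisons below, only the part of a region under peaks was compared. A change in signal height at a region covered in both groups would not be seen. No region passed the threshold. The region with the smallest p lay on chromosome 22 from 2849910 to 2850433 and was covered by 74.4% ± 43.3 (SD, n = 5) in familiar fish and 0% ± 0 (n = 5) in controls. Peaks touched it in 4 of 5 kept familiar 30 libraries and in no kept library of the other groups, and the same held for chromosome 6 from 32979780 to 32980032 (70.8% ± 41.7 against 0% ± 0). A region on chromosome 4 from 16492687 to 16493398 was covered by 90.8% ± 8.11 in familiar fish and 11.5% ± 25.6 in controls. On chromosome 20 from 14949439 to 14950199 the values were 65.4% ± 39.9 and 0% ± 0. The opposite order was measured on chromosome 22 from 18042014 to 18042420, with 0% ± 0 in familiar fish and 82.4% ± 11.6 in controls. The lowest limma adjusted p over all 52924 tested regions was 0.395. At an unadjusted p under 0.05 limma gave 1586 regions, of which 912 were higher and 674 lower in familiar fish, where 2646 are expected with no difference. The direction of this split is not stable: it was 304 higher and 1440 lower with all 23 libraries, 176 and 205 with only peaks of a -log10 q of at least 5, 756 and 907 without control 30 replicate 2, and 980 and 982 without control 30 replicate 4. Fisher's exact test of presence called 0 regions and gave 245 at that unadjusted level. With these group sizes at least 8401 would be needed for any to pass adjustment, so the 0 carries no weight. The count of 0 became 1 without familiar 30 replicate 1, without familiar 30 replicate 4 or without control 30 replicate 2, and 3 without familiar 30 replicate 6, each higher in familiar fish. It was 1, the region on chromosome 22 from 18042014, when only these 2 groups were fitted.

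Peak numbers and covered length at 30 did not separate the groups. Familiar libraries had 39023 ± 15726 peaks (SD, n = 6) and control libraries 44455 ± 1816 (n = 5; two-sided exact permutation test, p = 0.881). Peaks covered 76.1 ± 35.2 Mb in familiar and 89.4 ± 2.53 Mb in control libraries (exact permutation p = 0.788). Both differences turned positive without familiar 30 replicate 2, whose removal left 45413 ± 1725 peaks and 90.4 ± 4.86 Mb in the familiar group (n = 5). In each split that library largely sets the difference, so both p-values say little about the other libraries. The mean Jaccard index of covered bases, the shared length divided by the joint length, was 0.618 within groups and 0.626 between them (one-sided exact permutation p = 0.984). The difference of -0.00711 lay near the low end of the 252 splits, with libraries less alike within groups than in most other splits. The reason was not tested.

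**Figure D1:**
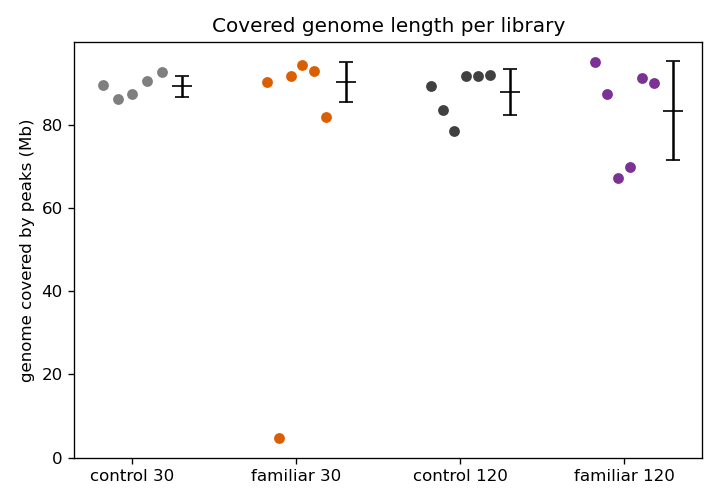
Each point is a library, placed by group on the horizontal axis and by the genome length its peaks covered, in Mb, on the vertical axis; black bars show the mean and SD of the kept libraries. One familiar 30 library lies at 4.70 Mb and all others lie between 67.3 and 95.2 Mb.

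The same comparison at 120 gave no region past the threshold either. The smallest p belonged to chromosome 5 from 21304503 to 21305665, covered by 57.2% ± 27.9 (SD, n = 6) in familiar fish and 0% ± 0 (n = 6) in controls. Peaks touched it in 6 of 6 familiar libraries and 0 of 6 control libraries. A second region on chromosome 5, from 24737592 to 24738338, was covered by 70.7% ± 38.0 in familiar fish and 5.38% ± 13.2 in controls. Values were lower in familiar fish on chromosome 18 from 4326856 to 4328130 (12.8% ± 19.95 against 81.4% ± 19.2), on chromosome 9 from 17943225 to 17944148 (0% ± 0 against 62.0% ± 31.0) and on chromosome 17 from 8214852 to 8216139 (0% ± 0 against 61.4% ± 39.0). The lowest limma adjusted p was 0.798, and 2302 regions had an unadjusted p under 0.05, with 372 higher and 1930 lower in familiar fish. With the covered length of each library as a covariate the split was 831 higher and 1195 lower, and the median difference over regions moved from -4.13 to -0.758 percentage points. Without familiar 120 replicate 3 it was 727 higher and 1217 lower with a median of -1.159 points, and without familiar 120 replicate 4 it was 542 and 1299. Fisher's exact test called 0 regions and gave 98 at the unadjusted level, too few for any to pass adjustment with these group sizes. The count was 1 without control 120 replicate 1, control 120 replicate 5 or familiar 120 replicate 3, and 2 when regions were built from bases covered in at least 11 libraries.

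Familiar libraries at 120 had 42683 ± 4632 peaks (SD, n = 6) and control libraries 45880 ± 2541 (n = 6; two-sided exact permutation p = 0.175). Covered length was 83.5 ± 11.9 Mb and 87.9 ± 5.54 Mb (exact permutation p = 0.42). The mean Jaccard index was 0.609 both within and between groups, with a difference of -0.000688 (one-sided exact permutation p = 0.519).

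Whether the familiarity difference itself changed between the labels 30 and 120 was tested as an interaction. No region passed, the lowest limma adjusted p was 0.9999, and 2194 regions had an unadjusted p under 0.05. The count was 1 without familiar 30 replicate 1 or without familiar 30 replicate 6.

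Control fish labelled 120 and 30 were compared to describe the time label without familiarisation. A 4119 bp region on chromosome 6 from 1088987 to 1093105 came closest to the threshold. It was covered by 9.32% ± 14.7 (SD, n = 6) at 120 and 81.4% ± 12.5 (n = 5) at 30, a difference of -72.1 ± 10.8 points (SE, limma adjusted p = 0.0528). It was present in 5 of 5 control libraries at 30, in 0 of 6 at 120, and in 3 of 5 familiar 30 and 4 of 6 familiar 120 libraries. Higher cover at 120 was measured on chromosome 3 from 6507369 to 6507755 (74.0% ± 16.98 against 0% ± 0) and on chromosome 12 from 10482794 to 10484061 (83.0% ± 8.60 against 18.1% ± 17.1). Lower cover was measured on chromosome 15 from 23935429 to 23936002 (0% ± 0 against 73.7% ± 14.9) and on chromosome 18 from 17419372 to 17420185 (0% ± 0 against 63.7% ± 22.9). These regions had limma adjusted p from 0.766 to 0.997. At an unadjusted p under 0.05 there were 1691 regions by limma and 158 by Fisher's exact test. Fisher's exact test called 0, since 158 are too few for any to pass its adjustment. The region on chromosome 6 passed with array weights (limma adjusted p = 0.039). It also passed without control 30 replicate 2, familiar 30 replicate 3, familiar 30 replicate 4 or control 120 replicate 4, with a count of 1 in each case. It did not pass in the other alternatives that gave it a value, with a limma adjusted p of 0.2197 with the range of fish numbers as a block, 0.272 with that block and covered length as a covariate, 0.7472 with all 23 libraries and 0.07137 when only these 2 groups were fitted. That fit called 3 regions, and this region was not among them.

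Familiar fish labelled 120 and 30 gave no region past the threshold. The regions on chromosome 22 from 2849910 and chromosome 6 from 32979780 again had the smallest p, at 0% ± 0 in 6 libraries labelled 120 (limma adjusted p = 0.221 for both). On chromosome 20 from 5416367 to 5416987, cover was 0% ± 0 (SD, n = 6) at 120 and 66.9% ± 39.7 (n = 5) at 30. The values at 30 were 72.8% ± 23.2 on chromosome 7 from 21095374 to 21095707 and 73.5% ± 19.4 on chromosome 13 from 13504390 to 13504902, where no library labelled 120 of familiar fish had a peak. Of 2215 regions at an unadjusted p under 0.05, 368 were higher and 1847 lower at 120. With covered length as a covariate these were 1151 and 843, with the range of fish numbers as a block as well 1068 and 912, and with all 23 libraries 717 and 474. Without familiar 120 replicate 3 they were 762 and 1352, with the median difference moving from -4.81 to -2.19 points. Fisher's exact test called 0 regions and gave 162 at the unadjusted level, again too few for any to pass adjustment. The count rose to 28, of which 27 were lower at 120, without familiar 30 replicate 6. It was 1 without familiar 30 replicate 1, familiar 30 replicate 4, control 30 replicate 2 or familiar 120 replicate 3, and 3 with regions built from bases covered in at least 11 libraries.

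**Figure D2:**
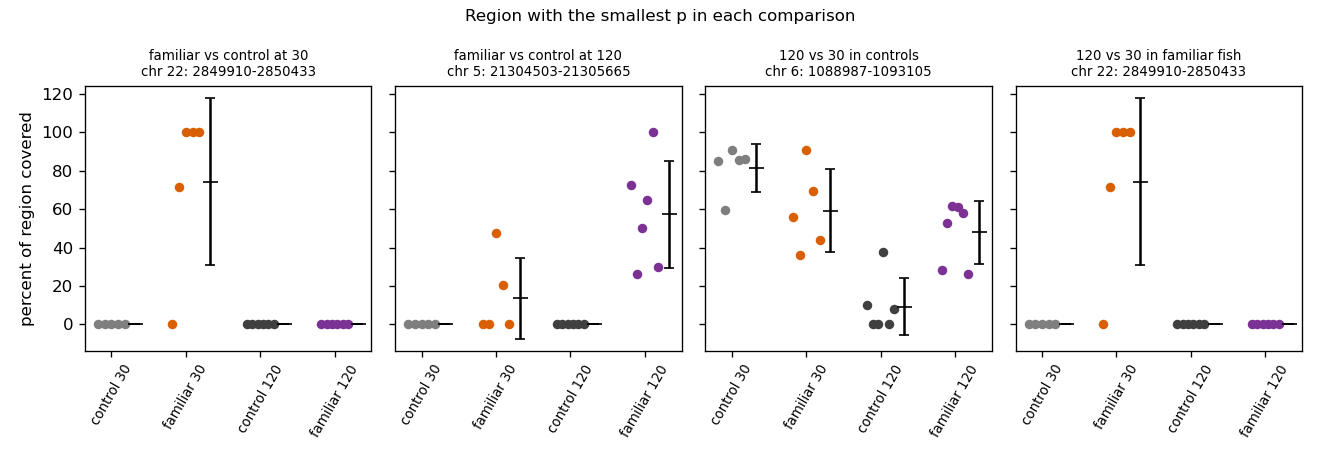
Percent of a region covered by peaks (vertical axis) in each kept library (points) of the 4 groups (horizontal axis), with mean and SD in black, for the region with the smallest p in each comparison. The region on chromosome 6 was covered by 9.32% in control 120 and 81.4% in control 30 libraries on average, and the region on chromosome 22 was covered in 4 familiar 30 libraries.

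Mean cover by length of region was compared in the same 4 pairs of groups. Regions of 10 kb or longer were covered by 79.9% ± 3.05 in familiar 30 (SD, n = 5), 78.5% ± 3.97 in control 30 (n = 5), 74.5% ± 9.99 in familiar 120 (n = 6) and 78.1% ± 3.89 in control 120 libraries (n = 6). Over 16 tests of 4 length classes, the lowest adjusted exact permutation p was 0.787. The share of the covered length lying on each of 24 chromosomes gave a lowest adjusted exact permutation p of 0.953 over 96 tests.

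Kept libraries overlapped with a median Jaccard index of 0.641 over 231 pairs, and the highest value was 0.681, so no list was a copy of another. Familiar 120 replicate 3 had a median index of 0.424 with 19 of the kept libraries, but 0.575 with control 30 replicate 3 and 0.485 with familiar 30 replicate 4. It held 2518 regions that were present in at most 3 of the other 21 kept libraries. Of these, 84.1% were present in control 30 replicate 3 and 59.8% in familiar 30 replicate 4, while the other 19 libraries had 1.39 to 8.98%. The low shares of those 19 are in part fixed by the choice of rare regions. For regions chosen alike from each of those 19 libraries, the library with the largest share held 17.4 to 25.7%. For control 30 replicate 3 and familiar 30 replicate 4, the largest shares were 60.5% and 58.3%, each held by another of the 3 libraries named here. Without these 3 libraries, left out after the data were seen, limma called 2 regions in the familiar comparison at 30, 2 at 120, 0 for the interaction, 0 for 120 against 30 in controls and 2 for 120 against 30 in familiar fish.

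**Figure D3:**
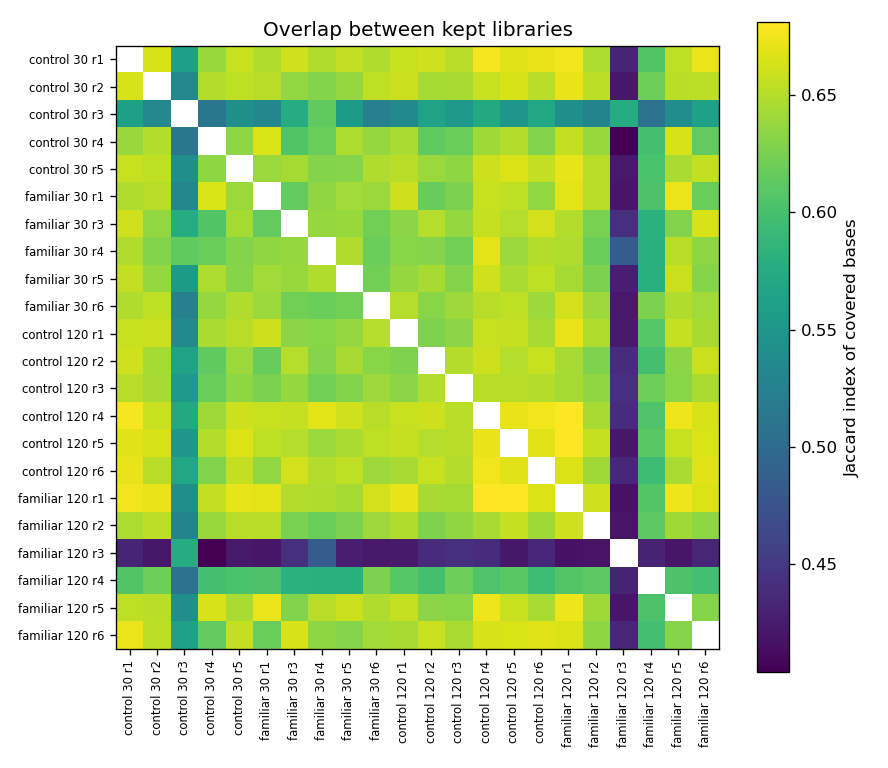
Jaccard index of covered bases (colour) for each pair of the 22 kept libraries, ordered by group on both axes; the diagonal is blank. Familiar 120 replicate 3 and control 30 replicate 3 form darker lines and share an index of 0.575.

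**Figure D4:**
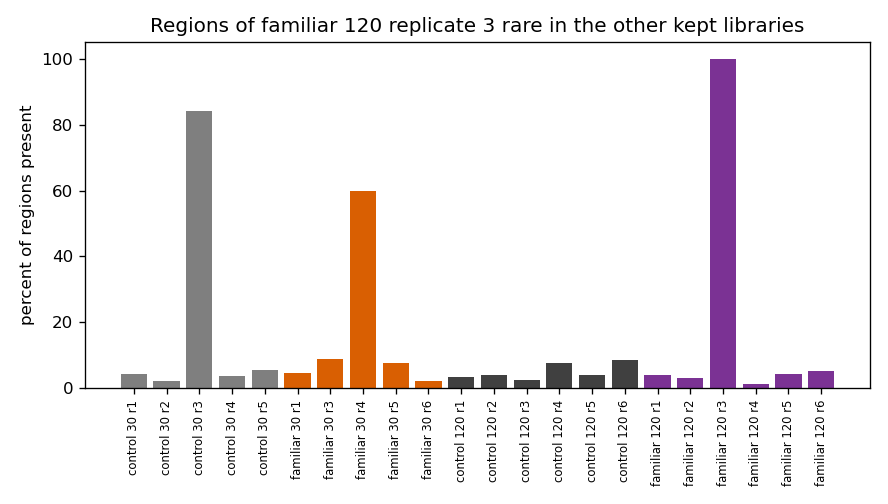
Percent (vertical axis) of the 2518 regions of familiar 120 replicate 3 that were rare in the other libraries, for each kept library (horizontal axis, coloured by group). Control 30 replicate 3 reaches 84.1%, familiar 30 replicate 4 reaches 59.8% and the other 19 libraries stay at or below 8.98%. The low values of those 19 follow in part from the choice of rare regions.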

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

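All tests in this part were chosen after the values were seen. Familiar 30 replicate 2 lay far from the other libraries of its group in 5 measures. It had 7077 peaks, 4.70 Mb of covered genome, a median peak width of 520 bp, 0 peaks of 10 kb or longer and a median Jaccard index of 0.0492 with the kept libraries. A lower yield of the same profile remains a candidate explanation, since 60.4% of its covered bases lay in regions present in every kept library. The same peaks placed at random gave at most 5.55%, and the equally many peaks with the highest -log10 q of the kept libraries gave 47.7 to 63.2%. The profile of the 3 libraries that share extra regions is left open: 0.0714% of its bases lay in those regions, between the 0.0145 to 0.0675% of equally many top peaks of the other 19 kept libraries and the 0.0901, 1.66 and 5.74% of the 3 libraries. No biological explanation was tested.

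Within their groups, familiar 120 replicate 3 (median Jaccard index 0.427) and control 30 replicate 3 (0.550) also lay far from the rest. Over the 24 sets of values tested for such a library, chance flags about 1 in 20: the rule marked 5% of 100000 simulated groups of 5 normal values and 5.02% of as many groups of 6. The tables argue against the treatment or time label as the cause, since the highest index of familiar 120 replicate 3 with its own group was 0.434, below the 0.485 and 0.575 with its partners of other groups. Their fish numbers all lie between 43 and 59, and the range as a whole can be neither supported nor excluded: the median index of familiar 120 replicate 3 with all 9 other kept libraries of that range was 0.4402, above the 0.404 to 0.439 measured outside it, but 0.433 over the 7 that are not its partners. Weak peaks called at greater depth may account for a part of the likeness. Read depth is unknown and q values depend on it, so the values do not decide how much. They show only that the likeness was not confined to peaks of a -log10 q under 5. With only peaks of a -log10 q of at least 5, the index of familiar 120 replicate 3 was 0.540 with control 30 replicate 3. It was 0.388 with familiar 30 replicate 4 and 0.315 to 0.358 with the other 19 kept libraries. The regions of familiar 120 replicate 3 that are rare in the others ranked at a median percentile of 48.6 by fold within its list, those of control 30 replicate 3 at 28.5 and those of familiar 30 replicate 4 at 16, against 9.31 to 12.8 in the other 19 libraries. All lie above that range, but none above the cut of 50 that was used first, and the comparison with the other libraries was added after 48.6 had been seen. Regions missing from familiar 120 replicate 3 had under 5% cover there and were present in at least 18 of the other 21 kept libraries. High shares in those 19 libraries are thus in part fixed by this choice. Of 1060 such regions, control 30 replicate 3 held 59.5%, less than any of those 19 libraries (at least 74.4%), but familiar 30 replicate 4 held 92.4%. Familiar 120 replicate 3 also had the fewest peaks (34714) and the shortest covered length (67.3 Mb) of the kept libraries. How far this accounts for its missing regions was not tested. A mixture with another tissue or cell population may be involved and cannot be told apart from differences between individual fish.

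The mitochondrial genome, which has no histones, was called as a peak in all 23 lists, over 16365 to 16686 bp. Its fold ran from 2.09 to 21.9. It had the highest fold of all peaks in 4 lists and was among the 10 highest in 8, while in control 120 replicate 4 it ranked 45237.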

How the results depend on the processing

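Leaving out 3 libraries that share regions was chosen after seeing the data, and all other alternatives before. At 30, the difference in peak number between familiar and control libraries was -5431 and turned to 958 without the low-yield library and to 1080 without that library and the 3 libraries. Each library left out in turn gave -7009 to 958. The difference in covered length was -13.3 Mb and turned to 0.969 Mb without the low-yield library, with a range of -17.0 to 0.969 Mb over single libraries left out. Leaving out the low-yield library thus turned both signs, but not under every alternative. For covered length the difference was negative again when the 3 libraries were left out as well. With only peaks of a -log10 q of at least 5, kept familiar 30 libraries had 12880 ± 1164 peaks (SD, n = 5). Control 30 libraries had 13116 ± 1672 (n = 5). At 120, the within minus between Jaccard difference of -0.000688 turned to 0.00104 without the 3 libraries. Leaving out single libraries turned it to 0.0111 (familiar 120 replicate 1), 0.00901 (replicate 2), 0.00104 (replicate 3), 0.00637 (replicate 4), 0.0104 (replicate 5) and 0.0122 (replicate 6), and the range over all single libraries left out was -0.0109 to 0.0122. None of these differences passed 0.05 under any alternative. Leaving out another familiar 120 library puts replicate 3, with its median index of 0.427, in a larger share of between pairs than of within pairs. This moves the difference up, and how far it accounts for the changes at 120 was not tested.

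Counts of regions past the threshold were 0 in all 5 comparisons and became the following. Fitting only the 2 groups compared gave 1 for familiar against control at 30 and 3 for 120 against 30 in controls. Array weights gave 1 for 120 against 30 in controls. Regions covered in at least 11 libraries gave 2 for familiar against control at 120 and 3 for 120 against 30 in familiar fish. Without the 3 libraries, the counts were 2 for familiar against control at 30, 2 at 120 and 2 for 120 against 30 in familiar fish. Leaving out single libraries gave 0 to 3 for familiar against control at 30, 0 to 1 at 120, 0 to 1 for the interaction, 0 to 1 for 120 against 30 in controls and 0 to 28 for 120 against 30 in familiar fish. In calls of named regions in their own comparison, the library left out had the lowest or highest cover among kept libraries of its group. At 30, the region on chromosome 22 from 2849910 had 0% cover in familiar 30 replicate 1, and its SE fell from 13.19 to 7.584 points without it. In controls, the SE of the region on chromosome 6 from 1088987 rose from 10.77 to 11.25 points without control 30 replicate 2. How far this accounts for the counts, which include other regions, was not tested. All other alternatives gave 0. For 20 pairs of a named region and comparison, 580 of 600 alternative values stayed on the same side of the threshold with the same sign, 20 passed it and 0 reversed. These regions were chosen for their smallest p in the same libraries, so the lack of reversals does not show stability. Named regions have no value where peaks with a -log10 q of at least 5, or bases in at least 11 libraries, redefine the regions. The planned promoter and gene list tests were not run. No paired analysis was possible because the replicate numbers only follow the order of deposit. Unknown read depth limits all comparisons of peak number and length.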

Other observations

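The tests in this part were chosen after the data were seen. Of the 2518 regions of familiar 120 replicate 3 rare in the other kept libraries, the longest lay on chromosome 18 from 24413410 to 24435463. It was covered by 100% in all 3 libraries that share extra regions. The next was on chromosome 4 from 20307796 to 20329630, with 100% in familiar 120 replicate 3 and control 30 replicate 3 and 96.5% in familiar 30 replicate 4. The 2518 regions lay on 24 chromosomes, and the chromosome with the most held 6.24% of them, against 4.95% of all regions. The longest region missing from familiar 120 replicate 3 lay on chromosome 23 from 15572010 to 15594313. It was covered by 1.9% there, 16.8% in control 30 replicate 3, 63.9% in familiar 30 replicate 4 and a median of 69.7% in the other 19 kept libraries.

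Other splits of the same libraries do not let chance be excluded for any comparison. Counts at an unadjusted p under 0.05 were taken over 100 splits for each comparison, the real split being 1 of the 100 and counted in the numbers here. Of these, 92 gave at least the 1586 regions of familiar against control at 30 (highest other 5838), and 46 gave at least the 2302 at 120 (highest other 5302). For the interaction 65 splits gave at least 2194 (highest other 5869). For 120 against 30, 94 splits gave at least 1691 in controls (highest other 3675) and 75 gave at least 2215 in familiar fish (highest other 6734). The medians of the other splits were 2251, 2221, 2607, 2000 and 2992 in the same order, where 2646 are expected with no difference. The highest split had several times the real count at 30 and for 120 against 30 in familiar fish, so counts vary widely between splits. The source of this variation was not tested. The adjusted count was 0 in each real split, while other splits called up to 47, 9, 3, 10 and 31 regions in the same order.

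Regions present in every library of 1 group and in none of the other numbered 13 for familiar against control at 30, 4 at 120, 14 for 120 against 30 in controls and 6 in familiar fish. The medians over the other splits were 26, 7, 15 and 12.

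A familiarity effect shared by both time labels would give like differences at 30 and at 120. Over the tested regions, which are not independent, the familiar minus control differences had a Pearson r of -0.0295 (permutation p = 0.93 over 99 redrawn labellings, which gave -0.258 to 0.305), and -0.0491 without the 3 libraries (permutation p = 0.43). This does not decide whether such an effect exists.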
